A study of Homo sapiens with 4 samples.

How the data were processed

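Mac-1 cells were measured on 4 one-colour Agilent arrays, 2 control and 2 SATB1 silenced, all on 1 slide and in 1 scan, so that no slide or scan batch divides the groups. Per the labels' protocols, cells were exposed to lentivirus for 24 hours and cultured for another 72 hours before total RNA was extracted, and RNA was linearly amplified and labelled with Cy3. The control group holds an untreated array and an array with sh0, and the groups and replicate numbers come from the labels.

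Per the file headers, the deposited scanner intensities were made by Agilent Feature Extraction 10.7.3.1, which subtracts and detrends the background within each array and gives a surrogate for signals at background; the headers name build hg19. The deposited series table holds log2 values whose quartiles are the same on all arrays, with a median of 6.19 in every column. Each column followed the log2 processed signal of its own array at r above 0.999, so its scale and direction could be found, while how the authors made it is not given in the sources used here. Surrogate values and background subtraction limit how low a signal can be measured, and amplification can change the relative level of transcripts.

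Spots marked as non-uniform or population outliers (79 to 100 per array) and control spots were left out, spots of a probe were averaged, and 65 probes with no unmarked spot on some array were dropped. No spot was saturated. The main values were log2 processed signals minus each array's 75th percentile of the same values. Genes were tested where a probe was well above background on both arrays of at least 1 group, which left 27533 probes for 19664 genes, of which 13730 have a gene symbol. The probe with the highest mean signal stood for a gene; 5651 genes had several tested probes, and 1331 of these had probes of opposite sign. Probes were named through a table of RefSeq accessions of GRCh38.p14, used for names only: 27294 by their accession, 136 by an accession list, 2278 by symbol and 436 by an older symbol, and 10856 kept the file's name. A gene well above background on no array of a group (815 in the controls, 119 in the silenced cells) is given as a bound. Where 1 array of a group was well above background, signals below their array's lowest signal well above background were raised to it, and the fold is given as a bound too; this was chosen after seeing the data.

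The groups were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, a prior standard deviation of 0.284 and 2.34 prior degrees of freedom. Gene lists, 28 written before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation and fry beside it. With an estimated correlation camera uses the 2 residual degrees of freedom, which leaves it little power. Differences between single arrays were described by counts of at least 2-fold and by correlations across genes, with 100 simulated sets for shared controls. Named genes were chosen by a rule fixed before the data were examined: SATB1 and CDKN1A, the 12 genes with a symbol leading in each direction among those changed at least 2-fold with no overlap between the groups (ordered by unadjusted p, since none passed), and the 4 members of each list with the smallest p, of which the text gives a selection; 2 members of these lists are not reported here. Other work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

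The same fit was tested on simulated data for this comparison, with 19664 genes, 2 against 2 arrays, the estimated prior, 200 changed genes and 20 draws. At an adjusted p under 0.05 it recovered 70.0% of genes changed by 4 log2 units and 88.3% of those changed by 6, with 4.15 false calls among 84.2 calls on average, and 4.98% of unchanged genes had an unadjusted p under 0.05. At an unadjusted camera p under 0.05, a list of 30 genes shifted by 1 log2 unit was found in 20 of 20 draws, and an unshifted one in 1. The simulated genes were independent and varied alike in both groups. In the data the estimated correlation was 0.93 in the list of G1/S and DNA replication and 0.88 in that of G2/M and mitosis. The silenced arrays also lay further apart than the controls, so these rates were not tested for such lists or spreads.

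Alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50 (with either normalization), the deposited series table, other filters on dim probes, the mean of a gene's probes or each probe alone, a variance trend with or without robust estimation, leaving out each array, the replicate number as a block, other thresholds and other list tests. Spike-in scaling with 10 E1A probes, normexp with local backgrounds above 100 replaced by the array's median, and 3 further gene lists were added after seeing the data. Gene positions relative to exons were not used here, since no annotation of the header's build was at hand.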

Results

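The series held 4 one-colour gene expression arrays of Mac-1, an established CD30-positive T-cell line that the labels describe as a large cell lymphoma of the primary cutaneous anaplastic kind. Cells of the SATB1 silenced group had received lentivirus carrying a short hairpin RNA (shRNA) against SATB1, a chromatin organiser that binds AT-rich DNA in T cells. Its 2 arrays carried different hairpins, sh2 for replicate 1 and sh4 for replicate 2. Of the 2 control arrays, replicate 1 came from untreated cells and replicate 2 from cells with the hairpin sh0. The treatment text speaks of controls with a scrambled hairpin without naming sh0. Each array gave 43376 non-control spots for 41000 probes. The 75th percentile of the processed signal was 787 for untreated cells, 739 for sh0, 676 for sh2 and 443 for sh4, and 66.1%, 64.7%, 70.5% and 68.1% of the spots in the same order were well above background. The number of arrays limits the precision, and the p-values measure only the spread between these samples.

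The comparison of silenced with control cells asked which genes differ when SATB1 is silenced, and the targeted gene was examined first. SATB1 was measured by 1 probe, on chromosome 3 from 18390257 to 18390316 (hg19). Its log2 signal relative to the array's 75th percentile was 1.71 in untreated cells and 1.76 with sh0, against 0.22 with sh2 and 0.97 with sh4. SATB1 was thus 2.21-fold lower in the silenced group (log2 fold change -1.14, SE 0.33, n = 2 against 2), and both silenced arrays lay below both controls. This difference did not pass the threshold of 0.05 over all genes (limma, adjusted p = 0.117). Without the sh2 array the adjusted p was 0.0129 (log2 fold change -0.77), and without the sh4 array it was 0.0119 (log2 fold change -1.52), each time on the assumption that the lone silenced sample varies like the controls; over all alternatives the adjusted p ranged from 0.000292 to 0.578. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 4.41-fold higher (log2 fold change 2.14, SE 0.35, adjusted p = 0.0638).

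**Figure D1:**
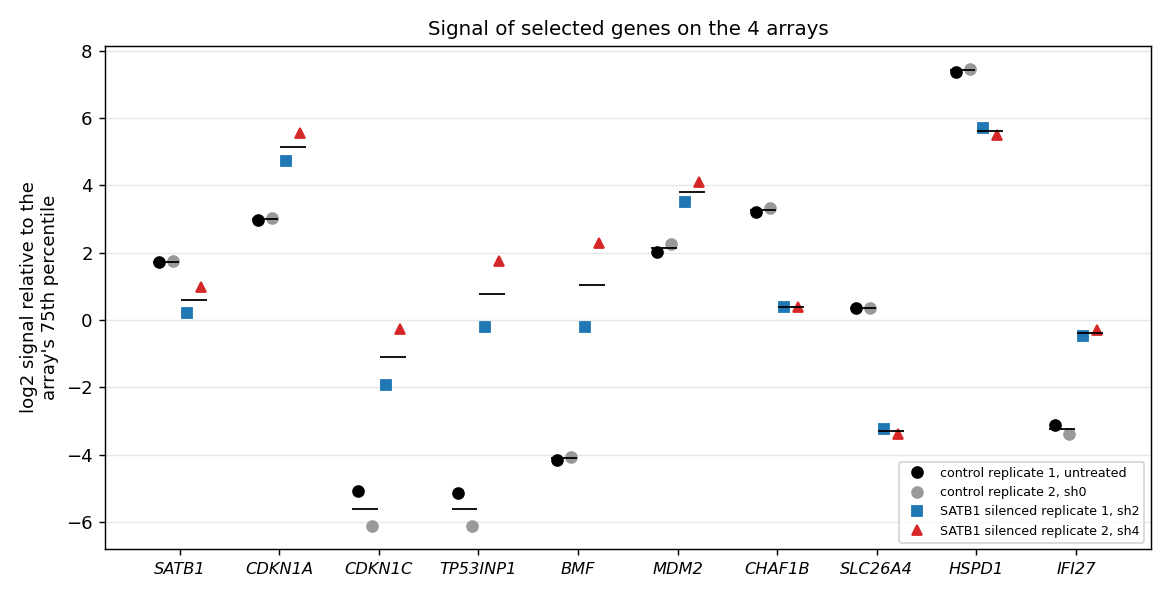
Log2 signal of 10 selected genes relative to each array's 75th percentile, with 1 point per array and a line at each group's mean of 2 arrays. SATB1 lies at 1.71 and 1.76 on the control arrays and at 0.22 and 0.97 on the silenced arrays.

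The groups stood apart in many genes, although no single gene passed the threshold. Of 19664 genes tested, 4879 differed at least 2-fold in the mean with no overlap between the groups, 2817 of them higher and 2062 lower in silenced cells. The groups did not overlap for 69.8% of the genes, where chance gives 33.3% for 2 against 2. No gene reached an adjusted p under 0.05 in limma, the lowest being 0.0576, while 6011 genes had an unadjusted p under 0.05 (3512 higher and 2499 lower, 983 expected by chance) and 2939 an adjusted p under 0.10. The spread behind these p-values is that between 2 different hairpins and between sh0 and untreated cells, not between repeats of 1 hairpin. At least 2-fold apart were 4305 genes between sh4 and sh2 but 330 between the controls, and limma pools both spreads. The higher share of those 6011 was 58.4%. With the arrays scaled to their spike-in controls instead, chosen after seeing the data, 17.3% of 4555 genes with an unadjusted p under 0.05 were higher, and the median log2 fold change of all tested genes moved from 0.22 to -0.48. The list medians over both silenced arrays below are therefore given relative to the median of all tested genes, except where said. Counts of higher and lower members, and medians of single arrays, are not, and they depend on the scaling. Of all 19664 genes tested, 11887 were higher on the main scale. The count past 0.05 was 81 without the untreated array, 48 without sh0, 12787 without sh2 and 7594 without sh4, again with a lone sample assumed to vary like the others.

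The genes leading the order of unadjusted p are described by size, and each had an adjusted p of 0.0576. Among the 12 leading higher genes, B3GALT4 64.1-fold, GPR155 13.6-fold and PBXIP1 11.9-fold higher were measured in both groups, as were H2AC6 (log2 fold change 4.17) and RASD1 (log2 fold change 3.42). RIPOR2, well above background on 1 control array, was at least 12.1-fold higher. B3GALT4 encodes a galactosyltransferase and RASD1 a Ras-like protein induced by glucocorticoid. H2AC6, a histone H2A gene, had another probe that differed the other way (log2 fold change -1.06). SELENOP, which encodes the secreted selenoprotein P, was not well above background on the control arrays and was at least 4.28-fold higher in silenced cells. By the same kind of bound, C1orf226 was at least 6.73-fold, ZBP1, a sensor of Z-form nucleic acid, at least 7.60-fold, LINC00886 at least 11.5-fold, MEIOB at least 8.95-fold and SPINK2 at least 3.74-fold higher. A bound sets the bright group's mean against the dim group's mean, with each dim array at its lowest signal well above background where the probe lay below it. Such a bound is approximate, since a probe not well above background can lie above that lowest signal, as that of TNFRSF4 did on a control array.

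Among the 12 leading lower genes, SLC26A4 12.7-fold, CHAF1B 7.39-fold, PA2G4 6.20-fold, PITHD1 5.78-fold, NT5DC2 5.69-fold, RABEPK 5.61-fold and MAGOHB 5.19-fold lower were measured in both groups, and GNRHR2, well above background on 1 silenced array, was at least 6.55-fold lower. The log2 fold changes of the tested probes ranged from -2.63 to -1.70 for PA2G4, 2.46 to 5.03 for RIPOR2 and 2.40 to 3.36 for ZBP1. SLC26A4 encodes the anion exchanger pendrin, and CHAF1B a subunit of the histone chaperone that assembles nucleosomes behind the replication fork. On the silenced arrays TFEC, PRSS58, FAM98B and LRRC2 were not well above background, and they were at least 5.86-fold, 4.75-fold, 4.69-fold and 5.64-fold lower. The LRRC2 probe holds a GAGAGAGAGA repeat, and the 16 tested probes with this repeat had a median log2 fold change of -1.83.

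Cell cycle genes were lower in silenced cells as a group. All 34 genes of the G1/S and DNA replication list were lower, 30 of them with an unadjusted p under 0.05 and 25 after adjustment over the list alone, and none passed over all genes. Their median lay at -2.46 log2 relative to all genes (camera adjusted p = 2.15e-15, and adjusted p = 0.698 with an estimated correlation). CHAF1B was 7.39-fold and FEN1, a flap endonuclease, 6.30-fold lower, and CCNE2 (cyclin E2) was not well above background on the silenced arrays and was at least 3.48-fold lower. Of 35 genes of G2/M and mitosis, 34 were lower, but 2 of these had an unadjusted p under 0.05 and none passed over the list alone (median -1.88 relative to all genes, camera adjusted p = 8.91e-06, and adjusted p = 0.823 with an estimated correlation). The mitotic checkpoint gene MAD2L1 was 6.02-fold lower, TOP2A 3.60-fold and PLK1 3.31-fold lower, while the phosphatase gene CDC25B was 1.85-fold higher. Relative to the control mean the log2 difference was -1.63 with sh2 and -3.55 with sh4 for MAD2L1, -0.998 with sh2 and -2.70 with sh4 for TOP2A, and -0.83 with sh2 and -2.63 with sh4 for PLK1. The silenced arrays differed from each other in these lists. The G1/S median was -1.35 with sh2 and -3.17 with sh4 relative to the controls, and the G2/M median was -0.30 with sh2 and -2.89 with sh4. In 34 of the 35 G2/M genes sh4 lay below sh2, and this difference between single arrays was not tested.

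Cell cycle inhibitors and p53 targets included higher members. Of 7 CDK inhibitors tested, 5 were higher, and 3 passed adjusted over the list alone: CDKN1A, CDKN1B (p27), 2.99-fold higher, and CDKN1C (p57), at least 17.9-fold higher and well above background on 1 control array. CDKN3 had a log2 fold change of -1.63 (SE 1.36), and as a whole the list did not pass (camera adjusted p = 0.159, and adjusted p = 0.698 with an estimated correlation). Of 25 p53 target genes, 23 were higher, 9 with an unadjusted p under 0.05 and 5 adjusted over the list alone, and 1 lower gene had an unadjusted p under 0.05 (median 0.51 relative to all genes, camera adjusted p = 0.0127, and adjusted p = 0.823 with an estimated correlation). Without the sh4 array the adjusted p of the list was 0.0507. TP53INP1, a stress-response gene, was at least 67.0-fold higher with 1 control array well above background, MDM2, the ubiquitin ligase of p53, 3.16-fold and RRM2B, a ribonucleotide reductase subunit, 2.21-fold higher. Among 29 regulators of apoptosis 24 were higher, 8 with an unadjusted p under 0.05 and 5 adjusted over the list alone (median 0.37 relative to all genes, camera adjusted p = 0.0139, and adjusted p = 0.698 with an estimated correlation). Not set against all genes, the median of this list was 0.58 (0.34 with sh2 and 0.80 with sh4, relative to the control mean), and -0.11 with spike-in scaling. The pro-apoptotic BMF was 35.4-fold higher, BIK at least 4.05-fold and CASP10 5.92-fold, and XIAP, an inhibitor of apoptosis, was 3.29-fold higher. Relative to the control mean the log2 difference was 0.35 with sh2 and -3.60 with sh4 for CDKN3, and 3.89 with sh2 and 6.40 with sh4 for BMF. With control signals as measured rather than bounded, it was 5.40 with sh2 and 7.37 with sh4 for TP53INP1, and 3.66 with sh2 and 5.32 with sh4 for CDKN1C.

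Interferon-stimulated and antigen presentation genes lay above the remaining genes. Of 45 interferon-stimulated genes 37 were higher, 18 of them with an unadjusted p under 0.05 and 4 adjusted over the list alone, and 1 lower gene had an unadjusted p under 0.05. The median was 0.88 relative to all genes (camera adjusted p = 0.00364, and adjusted p = 0.698 with an estimated correlation). IFI27 was 7.25-fold higher, IFI6 5.04-fold, EPSTI1 3.89-fold and SAMD9 3.53-fold, whose probes had log2 fold changes of 1.05 to 1.96. The median of this list on the sh0 array relative to untreated cells was -0.12, against 0.89 for sh2 and 1.37 for sh4 relative to the controls. These medians are not set against all genes, and the order of sh2 and sh4 depends on the scaling. Of 16 genes of HLA class I and antigen presentation 15 were higher, 7 of them adjusted over the list alone (median 0.58 relative to all genes, camera adjusted p = 0.00736, and adjusted p = 0.698 with an estimated correlation; adjusted p = 0.103 without the sh2 array), with B2M, the light chain of class I molecules, 2.76-fold, HLA-F 2.33-fold and TAP2, a subunit of the peptide transporter, 2.11-fold higher (log2 fold changes of its probes 0.44 to 1.07). The 15 tested HLA class II genes did not pass (camera adjusted p = 0.897, and adjusted p = 0.991 with an estimated correlation).

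Lymphocyte genes were higher and lower within the same lists. The type 1 and type 17 cytokine list had 18 of 23 genes higher (median 0.69 relative to all genes, camera adjusted p = 0.0269, and adjusted p = 0.698 with an estimated correlation; adjusted p = 0.109 without the sh2 array), and adjusted over the list alone 6 were higher and 1 lower. TBX21, the T-box factor of type 1 cells, was 3.26-fold and STAT4 4.44-fold higher, IL18RAP at least 3.64-fold higher, and the receptor gene IL12RB2 3.16-fold lower. The type 2 and IL-9 list missed the threshold with 8 of 10 genes higher (camera adjusted p = 0.0963, and adjusted p = 0.698 with an estimated correlation). It passed with fry (adjusted p = 0.0101), without the untreated array (adjusted p = 0.0190), without sh0 (adjusted p = 0.0224), with single probes (adjusted p = 0.0335) and with spike-in scaling (adjusted p = 0.00328). In it MAF, a transcription factor, was 10.1-fold, CSF2 (GM-CSF) 5.27-fold, the chemokine gene CCL1 3.91-fold and GATA3 2.67-fold higher. T-cell identity genes did not pass as a group (camera adjusted p = 0.0963, and adjusted p = 0.698 with an estimated correlation), but did after quantile normalization (adjusted p = 0.0456) and with fry (adjusted p = 0.0370), with PTPRC (CD45) 2.44-fold higher and ETS1 4.78-fold lower. Neither did the 23 tested genes of adhesion and migration (camera adjusted p = 0.144, and adjusted p = 0.698 with an estimated correlation), although they did with fry (adjusted p = 0.0337), of which ITGA5 was 3.29-fold and ITGB7 3.39-fold higher. The list of anaplastic lymphoma, activation and cytotoxic markers did not pass (camera adjusted p = 0.738, and adjusted p = 0.919 with an estimated correlation). GZMA (granzyme A) was at least 6.11-fold and BATF3 3.99-fold lower, and TNFRSF4 2.68-fold higher, with GZMA well above background on 1 silenced array and TNFRSF4 on 1 control array. Relative to the control mean the log2 difference was 2.59 with sh2 and 4.08 with sh4 for MAF, -1.01 with sh2 and -2.98 with sh4 for BATF3, and 0.80 with sh2 and 2.04 with sh4 for TNFRSF4. The log2 fold changes of the tested probes ranged from -2.26 to -0.94 for ETS1, 2.15 to 2.95 for STAT4 and 3.34 to 3.98 for MAF. TNFRSF8, which encodes CD30 and was picked after its values were seen, had log2 signals of 7.19 and 7.12 in the controls, 6.78 with sh2 and 5.09 with sh4 (log2 fold change -1.22, adjusted p = 0.238).

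The lists of chromatin partners, heat shock proteins, cholesterol biosynthesis and hypoxia had more lower than higher members, and their calls varied with the setting. Among 30 chromatin partners and relatives of SATB1, 20 were lower, 7 of them and 2 higher ones with an unadjusted p under 0.05, and adjusted over the list alone 0 lower and 1 higher passed (median -0.57 relative to all genes, camera adjusted p = 0.0127, and adjusted p = 0.698 with an estimated correlation). The lamin gene LMNB1 was 7.15-fold, DNMT1, the maintenance DNA methyltransferase, 2.88-fold and the cohesin gene SMC3 2.15-fold lower, while the acetyltransferase gene KAT2B was 5.07-fold higher. After quantile normalization the chromatin list no longer passed (adjusted p = 0.159). Of 15 heat shock proteins 10 were lower, and adjusted over the list alone 5 lower and 2 higher ones passed (median -0.75 relative to all genes, camera adjusted p = 0.0348, and adjusted p = 0.823 with an estimated correlation), with HSPD1 3.50-fold, HSP90AB1 3.06-fold and HSPE1 2.69-fold lower and HSPA2 2.06-fold higher. The heat shock call was lost without the sh4 array (adjusted p = 0.309) and with spike-in scaling (adjusted p = 0.115). Cholesterol biosynthesis (17 of 23 lower, median -0.57, camera adjusted p = 0.0380, and adjusted p = 0.823 with an estimated correlation) and hypoxia and glycolysis (22 of 32 lower, median -0.60, camera adjusted p = 0.0482, and adjusted p = 0.714 with an estimated correlation) also passed. HK2, a hexokinase gene, was 5.86-fold lower, whereas TM7SF2, a sterol reductase gene, was 2.81-fold and ALDOC, an aldolase gene, 4.78-fold higher. All 9 tested globin and erythroid genes were higher (median 0.49, camera adjusted p = 0.0482, and adjusted p = 0.714 with an estimated correlation), and HBZ, the embryonic zeta globin gene, was at least 2.82-fold higher with 1 control array well above background. Among 10000 random lists of genes of like signal, the globin median lay at percentile 78.1 with sh2 and 76.1 with sh4. It lay at percentile 94.3 for sh0 minus untreated, so these genes hardly stood out from others as dim. After quantile normalization the adjusted p was 0.170 for cholesterol biosynthesis, 0.159 for hypoxia and 0.532 for globin genes, and without the sh4 array 0.662, 0.165 and 0.309, so that none of these 3 calls held. Without the untreated array it was 0.138 for cholesterol biosynthesis and 0.0978 for globin genes. Lists of amino acid and unfolded protein stress (camera adjusted p = 0.0739, and adjusted p = 0.823 with an estimated correlation) and cytosolic ribosomal proteins (camera adjusted p = 0.0981, and adjusted p = 0.907 with an estimated correlation) missed the threshold, and in the former PSAT1 was 6.08-fold and SLC7A5 5.32-fold lower. The amino acid list passed without a filter on dim probes (adjusted p = 0.00897), with probe means (adjusted p = 0.0365), with single probes (adjusted p = 0.0141) and with the normexp setting added after seeing the data (adjusted p = 0.0211). Relative to the control mean the log2 difference was -1.86 with sh2 and -3.82 with sh4 for LMNB1, -1.66 with sh2 and -3.44 with sh4 for HK2, and -1.81 with sh2 and -3.02 with sh4 for SLC7A5. The log2 fold changes of the tested probes ranged from -2.41 to -1.01 for SLC7A5 and -2.45 to -1.81 for HSPD1.

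Of 27 lists with at least 5 tested genes, 12 passed with the preset correlation of 0.01, none with an estimated correlation, and 6 with fry, which asks whether a list moves one way on balance. Failing with an estimated correlation says little here, since that version of camera has 2 residual degrees of freedom. HLA class I and chromatin partners had estimated correlations of -0.061 and -0.019, below the preset one. Their unadjusted camera p still rose from 0.00109 to 0.0727 and from 0.00281 to 0.0770. Passing with the preset correlation, in turn, does not allow for estimates such as 0.93 for G1/S. Of the 12, 9 did not pass with fry, where the adjusted p was 0.169 for G1/S, 0.479 for G2/M, 0.0976 for interferon-stimulated, 0.230 for p53 target, 0.0976 for apoptosis, 0.378 for heat shock, 0.692 for cholesterol, 0.452 for hypoxia and 0.169 for globin genes. With the filter to probes well above background on all 4 arrays the adjusted p was 0.0544 for the type 1 and type 17 list, 0.0544 for heat shock, 0.0577 for cholesterol, 0.102 for hypoxia and 0.0601 for globin genes. With a robust variance trend 8 lists passed, and among those that no longer did was chromatin partners, where the adjusted p was 0.0507. With planned normexp, which failed on the silenced arrays, it was 0.233 for HLA class I, 0.603 for interferon-stimulated, 0.576 for p53 target and 0.259 for type 1 and type 17 genes. The other lists that did not pass were small RNA pathway (camera adjusted p = 0.821), oxidative phosphorylation (0.505), NF-kB and inflammatory response (0.505), immediate early genes (0.821), myeloid (0.133), epithelial (0.486) and B-cell markers (0.990). Among lists that did not pass, the adjusted p without the sh4 array was 0.0147 for CDK inhibitors, 0.0326 for NF-kB and 6.61e-04 for oxidative phosphorylation genes. Without sh2 it was 0.0403 for amino acid stress and 0.0161 for ribosomal proteins, without the untreated array 0.0152 for amino acid stress, and without sh0 0.0231 for myeloid markers. With single probes it was 0.0335 for CDK inhibitors and 0.0439 for myeloid markers, with a variance trend 0.0377 for ribosomal proteins, with normexp and quantile normalization 0.00348 for oxidative phosphorylation genes, and with spike-in scaling 0.0216 for CDK inhibitors and 0.0440 for myeloid markers. With planned normexp it was 3.60e-04 for amino acid stress and 0.0237 for myeloid markers. In immediate early genes MYC was 3.55-fold lower by its brighter probe, while another probe had a log2 fold change of 0.48. For anaplastic lymphoma, B-cell, small RNA, NF-kB and oxidative phosphorylation genes the signs of the median, the mean and the tests differed. Fibroblast and endothelial markers had 4 tested genes and were not tested as a list, and in it FBN1 (fibrillin 1) was at least 19.0-fold higher with 1 control array well above background.

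**Figure D2:**
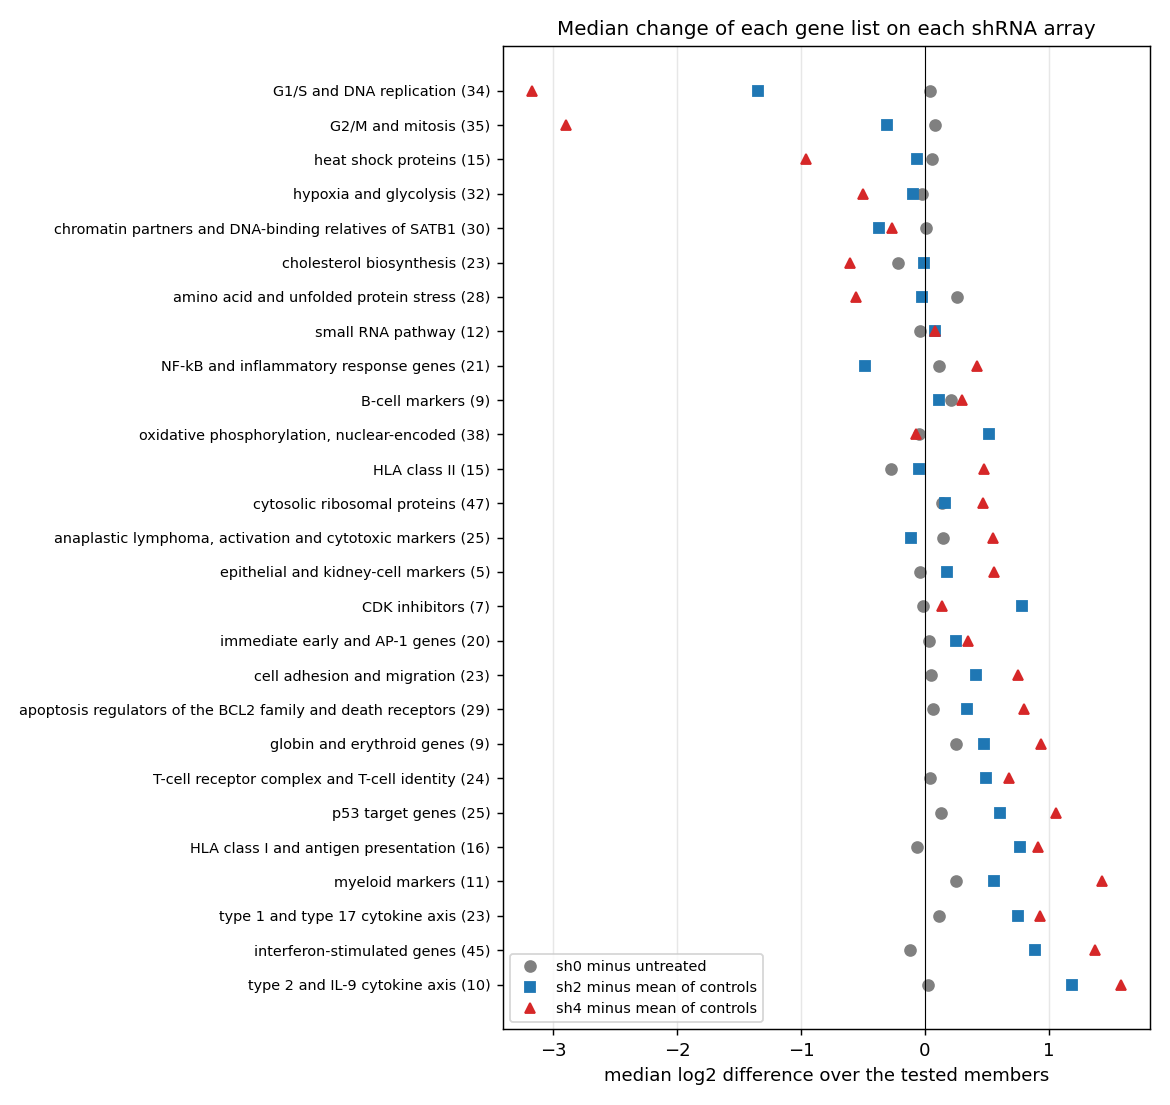
Median log2 difference over the tested members of each gene list (numbers in brackets), for sh0 minus untreated and for sh2 and sh4 minus the mean of the controls, with 1 array per hairpin. G1/S genes lie at -1.35 with sh2 and -3.17 with sh4, and interferon-stimulated genes at 0.89 and 1.37. The medians are not set against all genes.

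Whether both hairpins went with differences in the same genes was examined from differences that share no array. Across the 19664 genes, which are not independent replicates, sh2 minus untreated correlated with sh4 minus sh0 at r = 0.67 (Spearman's rho = 0.64). Of all tested genes 76.1% had the same direction in both differences, and of the 2736 genes at least 2-fold apart in both, 97.4% did. Both were at least 2-fold higher for 1577 genes, where independent lists of these sizes would share 508, and both lower for 1088, where they would share 248. With both hairpins set against the mean of the controls, r was 0.70 and the covariance 0.782, against 0.33 and 0.0258 for simulated unchanged arrays with shared controls. The covariance without a shared array was 0.760. The hairpins also differed from each other at least 2-fold in 4305 genes.

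**Figure D3:**
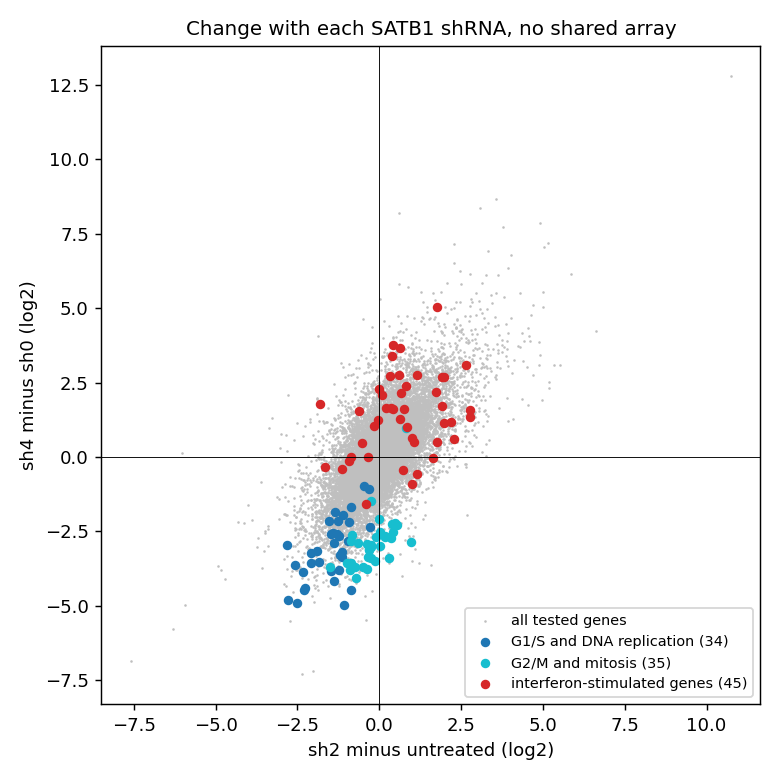
Log2 difference of each tested gene with sh2 (minus untreated, horizontal) and with sh4 (minus sh0, vertical), 1 point per gene, 3 gene lists coloured. The correlation across genes is 0.67.

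The control arrays, which differ in transduction by their labels, were close to each other. Only 330 genes (1.68%) differed at least 2-fold between sh0 and untreated cells, 167 higher and 163 lower with sh0, and the arrays correlated at r = 0.995 across genes. Between silenced and control arrays 3993 genes (sh2 minus untreated), 4040 (sh2 minus sh0), 7223 (sh4 minus sh0) and 7488 (sh4 minus untreated) differed as much. Between the silenced arrays 4305 did (sh4 minus sh2). No test was made, since each kind of control had 1 array. The labels do not say how much vector the sh0 cells carried, so this closeness does not show that transduction has little effect.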

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

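The tests in this part were chosen after the results were seen. Some signals outside the expression comparison were higher on silenced arrays. The median signal of the E1A spike-in probes was 932 on the sh2 array and 1117 on the sh4 array, above the 880 and 878 of the untreated and sh0 arrays. The local background exceeded 100 at 47 spots of the sh2 array and 24 spots of the sh4 array, and at 0 spots of either control array. Its median was not higher on the silenced arrays, at 37 for untreated, 38 for sh0, 37 for sh2 and 34 for sh4.

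The brighter spike-ins went with a dimmer sh4 array, whose 75th percentile was 443 against 676 to 787 on the others, and with the larger change from the controls. This larger change was not confined to dim genes or to the array's scale. After quantile normalization, among the brighter 9832 genes, 3158 differed at least 2-fold from the control mean on the sh4 array and 1611 on the sh2 array, a ratio of 1.96 (95% bootstrap interval over genes 1.88 to 2.05). The interval covers the spread over genes, which are not independent, and not that between arrays. Other effects that may go with a dim array were not tested, so a lower signal cannot be excluded as a cause. Whether sh4 also silenced SATB1 less cannot be told apart from the scaling. SATB1 on sh4 minus sh2 was 0.75 with the 75th percentile and 0.82 after quantile normalization, but -0.12 with spike-in scaling. With 1 array per hairpin, the hairpin, the culture and the array stay open as sources of the difference.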

How the results depend on the processing

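Spike-in scaling and the normexp setting with replaced local backgrounds were chosen after seeing the data. The number of genes with an adjusted p under 0.05, reported as 0, stayed 0 with both filters on dim probes, probe means, single probes, variance trends and normexp with quantile normalization. It was 1 after quantile normalization, 1 in the deposited series table, 7 with spike-in scaling, 540 with the added normexp and 16628 with planned normexp, and 48 to 12787 when 1 array was left out, the lone sample then being assumed to vary like the others. At an adjusted p under 0.10 it was 2939. Planned normexp failed for a reason that its values show: at 33 spots of sh2 and 18 of sh4 the local background exceeded the spot, with a lowest difference of -56531 on sh4, and the 10th percentile of the corrected log2 signals was 10.2 on sh2 and 9.88 on sh4 against 5.99 and 6.02 on the controls. For the other changes the cause was not tested. With the replicate number as a block, the count was 39, and the lists passing went from 12 to 14; the correlation of deviations was 0.032 over 2 pairs, so the numbers were not taken to pair samples.

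SATB1 was lower under every alternative, from -1.84 with spike-in scaling to -0.77. With planned normexp its log2 fold change was -1.50 and it passed the threshold, and across left-out arrays it ranged from -1.52 to -0.77. Of 27 lists, 12 passed; 7 passed with the strict filter, 0 with an estimated correlation, 6 with fry, 8 with a robust trend and 9 to 15 with the others. G1/S, G2/M and apoptosis lists passed under each setting of normalization, filter, probe choice and left-out array, the apoptosis list with the opposite direction under planned normexp. The correlation between hairpins was 0.67, and 0.64 after quantile normalization, 0.64 in the deposited series table, 0.64 with normexp and quantile normalization, 0.51 without a filter, 0.64 with the strict filter, 0.70 against the mean of controls, 0.64 as Spearman's rho and 0.97 with planned normexp. The 330 genes at least 2-fold apart between the controls became 1647 without a filter, 137 with the strict filter, 41 with planned normexp, 41 with the added normexp and 10 with normexp and quantile normalization, 1083 at 1.5-fold and 43 at 4-fold.

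Log2 fold changes with a changed sign were, by setting: with planned normexp PRSS58 1.95, TFEC 1.88, GNRHR2 1.53, LRRC2 2.00, FAM98B 1.95, CCNE2 2.23, ETS1 0.0718, CD27 1.86, GZMA 1.64, IL12RB2 0.43, HLA-F -0.00339, HLA-DRA -0.35, CD74 -0.60, HLA-DQB1 -0.74, NSDHL 1.26, SDHA -0.31, NDUFB5 -0.0247, NDUFA1 -0.55, RPS12 -0.42, RPS3 -0.81, RPL31 -0.77, FCER2 0.45; with normexp and quantile normalization AHSP -1.35e-04, EPB42 -0.00932, CLDN7 -0.0191, VWF -0.0380; in the deposited series table CLDN7 -0.00614, VWF -0.27; after quantile normalization CLDN7 -0.00277, VWF -0.27; with probe means NR4A1 -0.37, RPS3 -0.22, CR2 -0.13; with spike-in scaling CD74 -0.17, HLA-DQB1 -0.25, NDUFA1 -0.0103, RPS3 -0.24, RPL31 -0.18, EPB42 -0.0775, PAX5 -0.20, CR2 -0.25, CD14 -0.23, KRT14 -0.27, CLDN7 -0.33, KRT8 -0.39, KRT18 -0.32, VWF -0.38. Across left-out arrays these ranged as follows: CDKN3 -3.60 to 0.35, KRT18 -0.25 to 1.00. Camera adjusted p of lists with a changed direction were with planned normexp apoptosis regulators 0.0357, B-cell markers 0.457, CDK inhibitors 0.576, cell adhesion and migration 0.199, cytosolic ribosomal proteins 4.22e-13, HLA class I 0.233, HLA class II 3.60e-04, immediate early and AP-1 genes 0.199, oxidative phosphorylation 1.70e-07, p53 target genes 0.576, T-cell identity 0.513; with normexp and quantile normalization cytosolic ribosomal proteins 0.342, small RNA pathway 0.7496; with the added normexp B-cell markers 0.833, HLA class II 0.853, immediate early and AP-1 genes 0.951; in the deposited series table cytosolic ribosomal proteins 0.464, small RNA pathway 0.642; after quantile normalization cytosolic ribosomal proteins 0.532, small RNA pathway 0.645; without a filter B-cell markers 0.842, HLA class II 0.815, immediate early and AP-1 genes 0.908; with the strict filter B-cell markers 0.910; with probe means HLA class II 0.733; with single probes HLA class II 0.359, small RNA pathway 0.509; with the replicate block HLA class II 0.968; with spike-in scaling cytosolic ribosomal proteins 0.636, epithelial and kidney-cell markers 0.977, HLA class II 0.548, oxidative phosphorylation 0.977, small RNA pathway 0.986. Across left-out arrays these were small RNA pathway 0.768 to 0.970, HLA class II 0.559 to 0.721, oxidative phosphorylation 6.61e-04 to 0.960, anaplastic lymphoma 0.354 to 0.924, B-cell markers 0.674 to 0.814, NF-kB and inflammatory response genes 0.0326 to 0.730. For named genes, 1753 values kept sign and side, 435 passed the threshold newly and 49 changed sign; for lists 350 kept both, 28 passed newly, 40 no longer passed and 41 changed direction. Signal near background limits genes such as PRSS58, TFEC and FAM98B to bounds.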

Other observations

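The lists of this part were written after the leading genes were seen, and the sh0 test of interferon genes after its result was seen; the tests of the 3 further lists and of the repeat probes were set before their values were seen. All 31 tested ribosome biogenesis genes were lower in silenced cells, 28 of them adjusted over the list alone, and none of the 31 passed over all genes. Their median lay at -2.08 log2 relative to all genes (camera adjusted p over 3 lists = 3.79e-17, and adjusted p = 0.364 with an estimated correlation). DDX21, a nucleolar RNA helicase, had a log2 fold change of -3.01 (SE 0.72), RRP12 -2.49 (SE 0.28), NOP56 -1.92 (SE 0.26) and PES1 -2.21 (SE 0.22), while POLR1A was at -0.045. Reduced growth may accompany the lower cell cycle genes, a possibility drawn from this list alone, with no growth measured. Of 47 tested cytosolic ribosomal protein genes, in contrast, 44 were higher, but their median was only 0.09 relative to all genes. After quantile normalization their median log2 fold change was -6.08e-05, or -0.08 relative to all genes. The count of higher genes thus depends on the scaling.

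Of 59 replication-dependent histone genes (H2AC6 left out, since it had been seen), 48 were lower, with a median of -1.35 relative to all genes (camera adjusted p = 5.29e-09, and adjusted p = 0.364 with an estimated correlation). This may reflect fewer cells in S phase, although the histone classes differed. Every tested H4 gene was lower. Most H2B genes changed little, such as H2BC9 (-0.057) and H2BC13 (-0.072), with H2BC5 at -2.01 and H2BC12 at 1.83. H1-5 had -3.22 and H3C4 -2.17, while H1-2 (2.63) and H2AC19 (2.82) were higher. Of 18 FOXO target genes outside the fixed lists 17 were higher, 13 of them adjusted over the list alone, with a median of 1.98 relative to all genes (camera adjusted p = 3.64e-06, and adjusted p = 0.364 with an estimated correlation). KLHL24 had 4.11, HBP1 3.29, TXNIP 2.13 and CITED2 1.91. FOXO activity is a candidate explanation of the higher CDKN1B, BMF and TP53INP1, from lists alone and with no protein measured. None of the 3 lists passed with an estimated correlation, a test with little power at 2 residual degrees of freedom.

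The median of the interferon-stimulated list was 0.89 with sh2 and 1.37 with sh4 relative to the controls, and -0.12 with sh0 relative to untreated cells. These medians are not set against all genes. Spike-in scaling moves every gene of an array alike. It took SATB1, relative to the controls, from -1.52 to -1.78 with sh2 and from -0.77 to -1.90 with sh4. The order of the hairpins in this list therefore depends on the scaling. The difference between hairpins, with 1 array each, was not tested. Over both silenced arrays the list passed camera, but not with an estimated correlation (adjusted p = 0.698) or fry (adjusted p = 0.0976), and 4 of 45 members passed adjusted over the list alone. The largest difference among all tested probes was at a probe with no genome position and no gene name in the file's annotation (log2 signals -6.72 and -6.19 in the controls, 4.01 with sh2 and 6.61 with sh4), at least 1856-fold. A response to transduction with any hairpin vector cannot be told apart from the silencing. The labels do not say whether the sh0 cells carried as much vector as the others, and the unnamed probe might detect delivered sequence that the sh0 array lacks, which no vector sequence used here can settle.

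The 16 tested probes holding GAGAGAGAGA were all lower on the silenced arrays (median -1.83, quartiles -4.33 and -0.34). Other probes of the same genes without the repeat, for 7 genes, had a median of -0.13 (quartiles -0.66 and 0.37), and 55 probes with only the shorter GAGAGAGA had -0.21, against 0.18 for all tested probes. The 9 probes holding CTCTCTCTCT had a median of 1.31. The repeat in the probe, rather than the level of the gene, may set these differences, LRRC2 among them, although 7 genes are few.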
